A study of Mus musculus with 62 samples.

How the data were processed

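Messenger RNA was sequenced from 62 mouse samples: primary prostate tumors (19), metastases of lung (11), bone (12), liver (5), lymph node (4) and brain (3), and normal lung (3), bone (3) and liver (2). The submitters' processing notes name poly-A selection, either of a pair of TruSeq kits, bcl2fastq 1.8.4, TopHat2 2.1.0 (for the brain samples TopHat, with no version), DESeq2 and the mouse genome mm9. Which kit each library received, the gene annotation, the counting tool and any filter are not given in the sources used here. The deposited table of 22432 genes is called normalized, and its values were read as log2 scaled counts. They include negative values, with a median of -3.12. In 2 libraries, normal liver 1 and normal liver 2, low values cluster within 0.2 of whole multiples of a step fitted on the linear scale. Reads per library are not stated and the precision that depth gives is unknown; the spread between samples was used instead. How the submitters made the scatter at low values is not given in the sources used here. Their genome is mm9 and the annotation at hand GRCm38, so genes were matched by symbol and no coordinates were used.

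Samples were grouped by title and source. The 3 brain metastases, whose tissue field says prostate, were kept as brain metastases. The labels give 14 combinations of age, castration and bone metastasis status for induced mice and the study description 11 mice, so no mouse could be assigned to a sample. Library names start with CJ (44) or CMZ (18). The comparisons, filter, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

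Each comparison was fitted to its own pair of groups with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend). Genes were tested where the value reached 10 on the linear scale, 3.32 on the log2 scale, in at least as many samples as the smaller group holds. P-values were adjusted by Benjamini-Hochberg over genes tested, and a gene was called at an adjusted p under 0.05. Each metastasis site was compared with primary tumor; bone, lung and liver metastases also with normal tissue, and bone with lung metastases. Within primary tumors, bone metastasis status and castration were fitted together. A gene lay beyond both tissues when both changes had the same sign and the larger p-value passed after adjustment. That adjustment and unadjusted counts include genes of opposite signs, so the error rate beyond both may exceed 0.05. Where a group mean lay under 3.32, every sample value under 3.32 was set to it before the change was computed, and the change is given as a lower bound.

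For 30 gene lists with 402 members, written from general knowledge, camera was run with a preset correlation of 0.01 and adjustment over the lists of a comparison. Ocstamp, Dcstamp and Map2 are not in the table (3 symbols). Lists cover prostate identity, epithelial, basal, mesenchymal, neuroendocrine, MYC, RAS-ERK, cell cycle, hypoxia, oxidative phosphorylation, interferon, MHC class I and bone-tropism genes and markers of host tissues and blood cells. Named were Pten, Kras and Nkx3-1; for each site the 8 largest rises and falls beyond both tissues; and the 5 largest rises and falls in comparisons with primary tumor and of bone with lung, taken from called genes above the median level. Within primary tumors, 8 in each direction were taken, or the 3 lowest p-values where fewer than 3 genes passed. Of each called list up to 4 members with the lowest p were eligible, and 2 of other lists. Predicted genes, antigen receptor segments and small RNAs were skipped. The table also holds 25 date-like names that could not be matched to genes, and none is named.

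Alternatives were no filter, quantile normalization, array weights, 1 fit over all groups, CJ libraries only, the prefix as a covariate, strata of age and castration with an estimated correlation, replicate numbers as blocks, and each replicate of small groups left out in turn. For primary tumors they were also lobe as a covariate, the other factor left out and intact mice only; for lists, fry and an estimated correlation. Added later were CMZ libraries only, values floored at 3.32, and removal of each library's trend with gene length, and leaving out the 4 CJ libraries whose correlation of expression with log2 gene length was -0.2 or lower. Of CMZ libraries 15 of 18 had such a correlation and were kept. Groups were also split at random, with 100 splits each and a fixed seed. Gene length effects were measured on 8031 genes. Pseudogene copies were counted as pseudogenes that share at least 50 words of 31 bases with a gene. The procedure was tested on simulated data, where genes shifted by 1, 2 or 3 log2 units were added to each layout. Tables and figures were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.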

Results

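Bulk poly-A RNA sequencing gave 1 expression value per gene for 62 mouse tissue samples of a prostate cancer model, in which tamoxifen switches on Cre recombinase from the Nkx3-1 gene, deletes parts of Pten and turns on an activated Kras allele and a fluorescent reporter. There were 19 primary prostate tumors and 11 lung, 12 bone, 5 liver, 4 lymph node and 3 brain metastases. Normal lung and bone had 3 samples each and normal liver 2. Of the primary tumors 13 came from intact and 6 from castrated mice, and 13 from mice with and 6 without bone metastasis. The 3 brain metastases, labeled with prostate as tissue, were grouped by title and source. Library names start with CJ (44) or CMZ (18). All samples of castrated mice and of liver have CMZ names. All intact primary tumor, lymph node, brain, normal lung and normal bone samples have CJ names. No label ties a sample to a mouse, so samples of 1 mouse were treated as independent and p-values may be too small or too large to an unknown degree. Read depth per library is not given in the sources used here.

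The table holds 22432 genes on a log2 scale, and each library had between 12636 (a lymph node metastasis) and 15158 (a brain metastasis) genes at or above the floor of 3.32, the log2 of 10. Genes whose mean lies above the median of the genes tested are called well expressed. Differences are log2 fold changes ± standard error from limma, levels are log2 means ± SD over samples, and a gene whose mean lies under the floor in a group has a lower bound on its fold change instead. List members are counted over all genes tested, and counts adjusted over the list alone are added where they differ. Relative to the median library, expression fell with gene length, with a correlation of -0.2 or lower, in 15 of 18 CMZ libraries and in 4 of 44 CJ libraries (primary tumor 5, lung metastasis 9, bone metastasis 1 and lymph node metastasis 3). Only these 4 CJ libraries are meant by the libraries apart; primary tumor 5 also had 12.1% of its signal in the ribosomal precursor Rn45s. As 5 of 6 castrated but 1 of 13 intact primary tumors and all 7 liver libraries had such a correlation, it runs with castration and with liver against primary tumor. Of the list calls below, those of marrow granulocyte and erythroid markers in bone metastasis, lung epithelium and basal epithelial markers in lung metastasis and hepatocyte markers in liver metastasis, each against primary tumor, hold with an estimated correlation between genes, and for each list the adjusted p with that correlation follows as estimated.

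**Figure D1:**
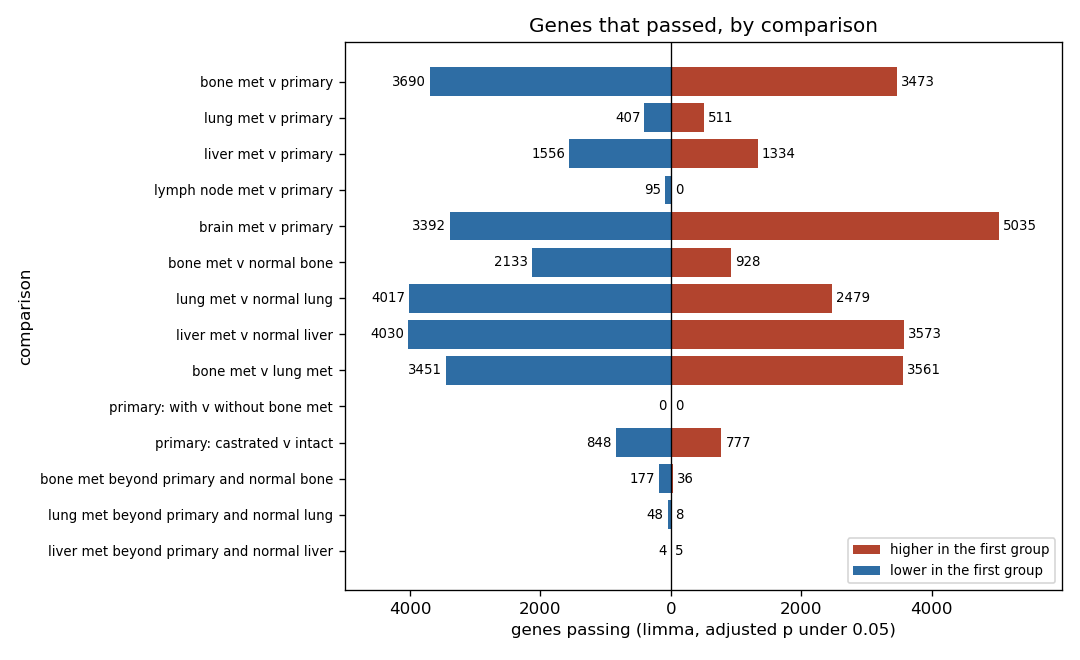
Number of genes that passed (limma, adjusted p under 0.05) in each comparison, with genes higher in the first group to the right and lower ones to the left. The counts run from 0 for bone metastasis status to 8427 for brain metastasis against primary tumor.

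Pten transcript, of which the deletion removes only a part, so that the whole-gene value checks nothing, was 11.48 ± 0.83 in bone metastases, 11.10 ± 0.89 in lung metastases and 10.95 ± 0.64 in primary tumors. Pten was lower in liver metastases than in normal liver (-1.43 ± 0.15, adjusted p = 0.000354), where Kras, whose activated allele cannot be told from the normal one in these values, was higher (1.70 ± 0.30, adjusted p = 0.00269). Kras was also lower in brain metastases than in primary tumors (-0.93 ± 0.38, adjusted p = 0.0445, -1.03 within CJ), a call lost without CMZ libraries. In the other comparisons with primary tumor and in those with normal bone or normal lung, Pten and Kras did not pass. Nkx3-1 was at or above the floor in 7 of 19 primary tumors and 3 of 12 bone, 1 of 11 lung, 1 of 4 lymph node and 3 of 3 brain metastases (4.61 ± 0.20). Its call in liver metastases (adjusted p = 0.0302) lies among values under the floor and gives no fold change.

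Bone metastases (n = 12) were set against primary tumors (n = 19) to ask how tumor tissue in bone differs from tissue in the prostate. Among well expressed genes the largest rises were in transcripts of bone marrow: Ngp, a granule protein of developing neutrophils, the calgranulins S100a8 and S100a9, the neutrophil protein Retnlg and the chitinase-like Chi3l3. Ngp was 17.30 ± 1.47 in bone metastases and 3.75 ± 2.91 in primary tumors (13.55 ± 0.86, adjusted p = 5.56e-14, 12.95 within CJ). S100a9 (9.23 ± 0.45, 9.26 within CJ), S100a8 (9.21 ± 0.47, 9.27 within CJ), Retnlg (8.22 ± 0.51, 8.28 within CJ) and Chi3l3 (7.89 ± 0.59, 7.13 within CJ, with reads that paralogs may share) rose as well. The largest falls among well expressed genes were in the carbonyl reductase Cbr2 (-6.38 ± 0.79, -6.84 within CJ), the epithelial adhesion protein Epcam (-6.36 ± 0.73, adjusted p = 1.54e-08, -6.62 within CJ), the tight junction protein Cldn4 (-5.49 ± 0.68, -5.17 within CJ), the basal keratin Krt14 (-5.37 ± 0.98, -4.37 within CJ) and the collagen Col15a1 (-5.09 ± 0.35, -5.21 within CJ). Krt14 was 10.88, 10.27 and 11.12 in bone metastases 6, 7 and 8 and at most 7.56 in the others. Of 14199 genes tested, 7163 passed, 3473 higher and 3690 lower in bone metastases; within CJ libraries 6206 passed.

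Marrow granulocyte markers moved together: 12 of 12 rose (median 10.96, 9.27 floored, camera adjusted p = 3.25e-16, 0.016 estimated). Camp, of neutrophil granules, was at least 3870-fold higher, and Prtn3, a neutrophil protease, 9.48 ± 0.49. Among erythroid markers 10 of 10 rose (median 9.69, 6.66 floored, camera adjusted p = 1.02e-13, 0.0139 estimated). Ermap, a red cell surface protein, was 7.53 ± 0.41. B cell markers rose, 9 of 9 (median 5.41, 3.01 floored, camera adjusted p = 3.03e-06, 0.274 estimated). Cd22 (2.40 ± 0.34) rose too. Among osteoclast markers of 7 members 6 rose, 0 fell and 1 did not pass (median 3.11, 2.88 floored, camera adjusted p = 0.000261, 0.281 estimated). The protease Ctsk, which degrades bone matrix, rose by 4.38 ± 0.52 and Mmp9 by 5.60 ± 0.56. Osteoblast and osteocyte markers gave a like count, of 8 members 6 rose, 1 fell and 1 did not pass (median 2.47, camera adjusted p = 0.0269, 0.313 estimated). The matrix protein Ibsp (5.19 ± 1.04) and the osteoblast transcription factor Sp7 (at least 9.49-fold higher) rose. Skeletal muscle markers were higher too, 9 of 9 rose (median 5.22, 4.66 floored, camera adjusted p = 0.000276, 0.384 estimated). Pvalb was at least 12-fold higher.

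Epithelial markers fell as a group: 14 of 14 (median -3.35, camera adjusted p = 7.67e-07, 0.281 estimated). Esrp1, a splicing regulator of epithelial cells, was at least 75.8-fold lower and the claudin Cldn7 at least 53.1-fold lower. For basal epithelial markers 8 of 8 fell (median -5.50, -4.81 floored, camera adjusted p = 4.26e-05, 0.274 estimated). Krt5 went from 11.04 ± 2.76 in primary tumors to under the floor in 12 of 12 bone metastases (at least 210-fold lower). Transcripts of RAS-ERK output went down, of 23 members 1 rose, 19 fell and 3 did not pass (median -1.16, 1 and 20 adjusted over the list alone, camera adjusted p = 8.52e-05, 0.384 estimated). Spry2 (-1.30 ± 0.17) and Etv1 (-2.57 ± 0.41) fell. Cell cycle genes rose, 25 of 25 (median 1.56, camera adjusted p = 1.64e-10, 0.298 estimated). Mcm5, of the replicative helicase, rose by 2.03 ± 0.26 and the kinase Bub1b by 1.73 ± 0.22. Normal bone had Mki67 at 14.38 or above, so marrow may add to this. Of 15 interferon response genes 0 rose, 13 fell and 2 did not pass (median -2.71, camera adjusted p = 9.11e-05, 0.384 estimated). Ifit3 (-4.98 ± 0.72) and Gbp2 (-1.90 ± 0.27) fell. Higher as lists were also MYC targets (18 rose, 2 fell, 30 did not pass, camera adjusted p = 0.00264), oxidative phosphorylation (10 rose, 0 fell, 16 did not pass, camera adjusted p = 0.0167) and T cell (8 rose, 0 fell, 2 did not pass, camera adjusted p = 0.00227), each with 0.384 or above estimated. Of the 18 lists called, lower ones also included hypoxia and glycolysis (1 rose, 8 fell, 5 did not pass, camera adjusted p = 0.00381), mesenchymal transition (0 rose, 5 fell, 7 did not pass, camera adjusted p = 0.0457, adjusted p = 0.0574 with quantile normalization, adjusted p = 0.0812 without the libraries apart, adjusted p = 0.0543 with the length trend removed), fibroblast (1 rose, 6 fell, 1 did not pass, camera adjusted p = 0.0313, adjusted p = 0.0533 without the libraries apart) and smooth muscle (0 rose, 6 fell, 1 did not pass, camera adjusted p = 0.00118), each with 0.313 or above estimated.

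Lung metastases (n = 11) against primary tumors put the same question for lung. Chi3l3, with reads that paralogs may share, rose most among well expressed genes (3.89 ± 0.54, adjusted p = 1.22e-05, 3.55 within CJ), followed by elastin Eln (3.62 ± 0.64, 4.2 within CJ), the lymphatic receptor Lyve1 (3.52 ± 0.48, 3.69 within CJ), the aldehyde dehydrogenase Aldh1a1 (2.86 ± 0.67, 2.56 within CJ, adjusted p = 0.0634 within CJ) and the hypoxia-inducible factor Epas1 (2.76 ± 0.37, 2.98 within CJ). Among well expressed genes the largest falls were those of lactoferrin Ltf (-4.68 ± 0.98, adjusted p = 0.00211, -4.71 within CJ), the immunoglobulin receptor Pigr (-4.42 ± 1.11, -4.49 within CJ, adjusted p = 0.0546 within CJ), the carbonic anhydrase Car12 (-4.10 ± 0.87, -3.85 within CJ), Krt14 (-3.87 ± 0.77, -3.25 within CJ) and Epcam (-3.86 ± 0.76, -3.80 within CJ). Of 14175 genes 918 passed, 511 higher and 407 lower, and 747 within CJ. Within CMZ, where only 2 lung metastases and 6 primary tumors remain, all from castrated mice, 3 passed.

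Lung epithelium markers rose: of 12 members 9 rose, 0 fell and 3 did not pass (median 5.38, 4.26 floored, 10 and 0 adjusted over the list alone, camera adjusted p = 1.49e-23, 0.00256 estimated). Surfactant protein genes Sftpc (8.86 ± 0.73) and Sftpa1 (at least 279-fold higher) and the club cell protein Scgb1a1 (9.17 ± 0.84) were among them. Endothelial markers were higher, of 9 members 8 rose, 0 fell and 1 did not pass (median 1.55, camera adjusted p = 3.41e-11, 0.0528 estimated). Pecam1 (1.55 ± 0.26) and Cdh5 (1.64 ± 0.28) rose. Among marrow granulocyte markers of 9 members 6 rose, 1 fell and 2 did not pass (median 2.45, 2.23 floored, 8 and 1 adjusted over the list alone, camera adjusted p = 2e-07, 0.0528 estimated). The fall was that of Ltf, and S100a9 rose by 2.42 ± 0.42. Higher too were erythroid (2 rose, 0 fell, 2 did not pass, camera adjusted p = 0.0134), B cell (2 rose, 0 fell, 3 did not pass, camera adjusted p = 0.000886) and T cell (1 rose, 0 fell, 9 did not pass, camera adjusted p = 0.0068), each with 0.167 or above estimated. Basal epithelial markers fell: of 8 members 0 rose, 5 fell and 3 did not pass (median -3.60, 0 and 6 adjusted over the list alone, camera adjusted p = 3.41e-11, 0.0481 estimated). Krt5 (at least 154-fold lower, with 11.04 ± 2.76 in primary tumors) and Krt17 (at least 36.6-fold lower) fell. Among epithelial markers of 14 members 0 rose, 6 fell and 8 did not pass (median -1.92, 0 and 8 adjusted over the list alone, camera adjusted p = 1.26e-06, 0.228 estimated). Elf3 (-2.95 ± 0.60) and Cdh3 (-2.10 ± 0.47) fell. Interferon response genes were lower, of 15 members 0 rose, 9 fell and 6 did not pass (median -2.04, 0 and 12 adjusted over the list alone, camera adjusted p = 5.55e-10, 0.231 estimated). Irf7 (-2.90 ± 0.61) and Isg15 (-2.50 ± 0.60) fell. No single member of the cell cycle list passed while the list was higher, of 25 members 0 rose, 0 fell and 25 did not pass (median 0.50, camera adjusted p = 1.33e-05, 0.491 estimated). Of the 14 lists called, lower ones also included MHC class I presentation (0 rose, 0 fell, 10 did not pass, camera adjusted p = 0.000277), hypoxia and glycolysis (0 rose, 2 fell, 12 did not pass, camera adjusted p = 0.000252), oxidative phosphorylation (0 rose, 0 fell, 26 did not pass, camera adjusted p = 0.00768, adjusted p = 0.2 with the length trend removed) and smooth muscle (0 rose, 1 fell, 6 did not pass, camera adjusted p = 0.00804, adjusted p = 0.0743 within CJ), each with 0.417 or above estimated.

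Liver metastases (n = 5, intact, CMZ) were compared with primary tumors, of which only the 6 from castrated mice are CMZ. Haptoglobin Hp (6.75 ± 0.74, adjusted p = 3.2e-07, 6.23 within CMZ) and transferrin Trf (5.79 ± 0.66, adjusted p = 5.94e-07, 5.30 within CMZ), both plasma proteins made by hepatocytes, were among the largest rises of well expressed genes. Ribosomal protein genes Rpl28, Rps7 and Rps23 also passed, but within CMZ they were 0.21, 0.07 and 0.02 (adjusted p = 0.675, 0.895 and 0.962). Ubb, with -4.91 ± 1.51 over all libraries, likewise turned to 0.12 within CMZ (adjusted p = 0.881). Falls kept within CMZ were those of Ltf (-6.35 ± 1.42, adjusted p = 0.00265, -5.81 within CMZ), Krt5 (-5.48 ± 1.18, -6.83 within CMZ), Cbr2 (-4.97 ± 1.16, -4.83 within CMZ) and Car12 (-4.77 ± 1.26, -5.43 within CMZ). Of 14945 genes 2890 passed, 1334 higher and 1556 lower; 1614 passed within CMZ, 1760 with the prefix as a covariate, 4613 without the 4 libraries apart, 2538 with the length trend removed, and 1884 without liver metastasis 1 or 1828 without liver metastasis 4.

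Hepatocyte markers rose, 12 of 12 (median 12.27, 10.53 floored, camera adjusted p = 4.7e-21, 0.0146 estimated). Hpx (11.35 ± 0.53) and Apoa2 (at least 708-fold higher) rose. Alb was also detected in primary tumors of castrated mice (8.88 ± 0.08), the only CMZ primary tumors. Cell cycle genes were higher, of 25 members 7 rose, 0 fell and 18 did not pass (median 0.88, 10 and 0 adjusted over the list alone, camera adjusted p = 1.06e-06, 0.605 estimated). Mcm7 (1.53 ± 0.33, 0.69 within CMZ) and Ccnb1 (1.60 ± 0.46, 0.90 within CMZ) rose. Also higher were MYC targets (15 rose, 0 fell, 35 did not pass, camera adjusted p = 5.15e-07) and oxidative phosphorylation (8 rose, 0 fell, 18 did not pass, camera adjusted p = 8.47e-07), each with 0.605 or above estimated. Their leading members moved less within CMZ, as in Fbl (2.54 ± 0.69, 0.35 within CMZ) and Ndufs3 (1.70 ± 0.45, 0.28 within CMZ). Basal epithelial markers fell, of 8 members 0 rose, 5 fell and 3 did not pass (median -4.69, -4.44 floored, 0 and 7 adjusted over the list alone, camera adjusted p = 0.000225, 0.605 estimated). Col17a1 (at least 64.1-fold lower, adjusted p = 0.0209 within CMZ) and the basal transcription factor Trp63 (at least 20.5-fold lower, adjusted p = 0.0177 within CMZ) fell. Among epithelial markers of 14 members 0 rose, 6 fell and 8 did not pass (median -2.19, 1 and 8 adjusted over the list alone, camera adjusted p = 0.032, 0.743 estimated, adjusted p = 0.115 within CMZ, adjusted p = 0.0597 without the libraries apart). Esrp1 fell by -5.40 ± 1.22, -5.50 within CMZ. Interferon response genes were lower, of 15 members 0 rose, 10 fell and 5 did not pass (median -2.63, 0 and 13 adjusted over the list alone, camera adjusted p = 2.51e-05, 0.605 estimated). Stat1 (-2.10 ± 0.48, -2.29 within CMZ) and Oasl2 (-3.06 ± 0.82, -3.30 within CMZ) fell. Stromal lists fell, namely fibroblast (0 rose, 4 fell, 4 did not pass, camera adjusted p = 0.0179), endothelial (0 rose, 4 fell, 5 did not pass, camera adjusted p = 0.00461) and smooth muscle (0 rose, 3 fell, 4 did not pass, camera adjusted p = 0.0179, adjusted p = 0.0597 without the libraries apart), each with 0.605 or above estimated.

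Lymph node metastases (n = 4) differed from primary tumors in 95 of 14961 genes, 0 higher and 95 lower. The basal keratin Krt5 was at least 210-fold lower, adjusted p = 0.00025, from 11.04 ± 2.76 in primary tumors to under the floor in 4 of 4 lymph node metastases. Pigr (-7.56 ± 1.78, adjusted p = 0.0451), Ltf (-6.92 ± 1.56, adjusted p = 0.0358), the epithelial transcription factor Ehf (-6.80 ± 1.50, adjusted p = 0.0318) and the serine protease Tmprss2 (-6.62 ± 1.19, adjusted p = 0.0114) fell too, and Pigr did not pass within CJ (adjusted p = 0.0826). With 1 library left out, 13 genes passed without lymph node metastasis 2, 1 without lymph node metastasis 3 and 30 without lymph node metastasis 4, and 38 without the libraries apart. Lymph node metastasis 3 and primary tumor 5 are both among the libraries apart. Flooring left 2 genes, 1 of them among the 95, and 6 of 100 splits of the samples, the real one included, called at least as many.

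Epithelial markers fell as a list, of 14 members 0 rose, 4 fell and 10 did not pass (median -3.65, 0 and 8 adjusted over the list alone, camera adjusted p = 6e-13, 0.12 estimated). Esrp1 (at least 32.7-fold lower, adjusted p = 0.0114) and Elf3 (-5.36 ± 1.05, adjusted p = 0.0162) fell. Basal epithelial markers did so too, of 8 members 0 rose, 3 fell and 5 did not pass (median -4.17, 0 and 6 adjusted over the list alone, camera adjusted p = 2.91e-10, 0.12 estimated). Krt17 was at least 24.6-fold lower. Cell cycle genes were higher as a list, of 25 members 0 rose, 0 fell and 25 did not pass (median 0.76, camera adjusted p = 3.19e-08, 0.493 estimated). Bub1b had 0.96 ± 0.39, not passing. Interferon response genes were lower as a list, of 15 members 0 rose, 0 fell and 15 did not pass (median -2.28, 0 and 8 adjusted over the list alone, camera adjusted p = 3.6e-07, 0.493 estimated). Irf7 had -2.59 ± 1.00, not passing. Also lower were lung epithelium (0 rose, 2 fell, 9 did not pass, camera adjusted p = 6.99e-05), smooth muscle (0 rose, 0 fell, 7 did not pass, camera adjusted p = 0.00257) and seminal vesicle (0 rose, 0 fell, 7 did not pass, camera adjusted p = 0.0178, adjusted p = 0.0581 without the libraries apart), each with 0.357 or above estimated. Sftpd, a surfactant protein that other epithelia express too, was at least 13-fold lower. Also higher were macrophage (0 rose, 0 fell, 9 did not pass, camera adjusted p = 0.00858, adjusted p = 0.0826 without the libraries apart) and adipocyte (0 rose, 0 fell, 6 did not pass, camera adjusted p = 0.0275, adjusted p = 0.079 without the libraries apart), each with 0.603 or above estimated. Csf1r had 0.79 ± 0.45, not passing. Quantile normalization moved the median of all genes by 0.11 here.

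Brain metastases (n = 3) had higher levels of transcripts of brain. The neuronal sodium pump subunit Atp1a3 rose by 8.60 ± 0.68, adjusted p = 9.2e-10, 8.82 within CJ, neuronal enolase Eno2 by 7.65 ± 0.58, adjusted p = 4.36e-10, 7.52 within CJ, and the glial pump Atp1a2 by 7.57 ± 1.23, 7.12 within CJ. The long RNA Meg3 (7.57 ± 0.89, 7.73 within CJ) and brain creatine kinase Ckb (6.99 ± 0.71, 7.59 within CJ) rose as well. Krt5 (at least 210-fold lower), Epcam (at least 277-fold lower), Pigr (-8.01 ± 2.01, -8.33 within CJ), Krt6a (at least 83.8-fold lower) and Krt14 (-7.94 ± 1.35, -7.21 within CJ) fell, Epcam from 11.52 ± 2.45 in primary tumors. Of 16153 genes 8427 passed, 5035 higher and 3392 lower, a share of 59.7% higher. Quantile normalization moved the median of all genes by -0.51 and the share higher to 40.5%, so directions of small changes depend on the scaling.

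Brain neuron and glia markers rose, 11 of 11 (median 10.41, 9.31 floored, camera adjusted p = 2.84e-06, 0.136 estimated). Gfap, the astrocyte filament, was 10.91 ± 1.09 and Mbp, a myelin protein, 6.13 ± 0.67. Neuroendocrine markers, which neurons also express, gave of 10 members 9 rose, 0 fell and 1 did not pass (median 9.13, 7.84 floored, camera adjusted p = 0.000128, 0.174 estimated). Chgb was at least 1030-fold higher. Cell cycle genes fell: 25 of 25 (median -2.81, camera adjusted p = 6.22e-09, 0.426 estimated). Mki67 (-3.73 ± 0.64) and Mcm6 (-3.26 ± 0.59) fell. Epithelial markers fell, 14 of 14 (median -5.67, -5.39 floored, camera adjusted p = 5.47e-08, 0.273 estimated). Basal epithelial markers fell as well, 8 of 8 (median -6.81, -5.49 floored, camera adjusted p = 0.000112, 0.426 estimated). Krt8 was -5.50 ± 0.63 and Itgb4 -4.18 ± 0.43. RAS-ERK output was lower, of 23 members 3 rose, 14 fell and 6 did not pass (median -1.81, 5 and 14 adjusted over the list alone, camera adjusted p = 0.0033, 0.426 estimated). Epha2 (-3.53 ± 0.42) and Spry1 (-2.14 ± 0.31) fell. TGF-beta and bone-tropism factors gave of 14 members 0 rose, 11 fell and 3 did not pass (median -2.80, camera adjusted p = 0.000112, 0.273 estimated). Jag1 fell (-3.18 ± 0.51). Also higher was oxidative phosphorylation (18 rose, 0 fell, 8 did not pass, camera adjusted p = 0.00522), with 0.595 estimated. Of the 16 lists called, lower ones also included interferon response (0 rose, 10 fell, 5 did not pass, camera adjusted p = 0.000808), MHC class I presentation (0 rose, 8 fell, 2 did not pass, camera adjusted p = 0.00509), fibroblast (0 rose, 5 fell, 3 did not pass, camera adjusted p = 0.00358) and smooth muscle (0 rose, 6 fell, 1 did not pass, camera adjusted p = 0.00509), each with 0.426 or above estimated. Lower too were mesenchymal transition (1 rose, 9 fell, 2 did not pass, camera adjusted p = 0.00522), MYC targets (2 rose, 14 fell, 34 did not pass, camera adjusted p = 0.00651), hypoxia and glycolysis (0 rose, 6 fell, 9 did not pass, camera adjusted p = 0.00651) and osteoclast (1 rose, 4 fell, 2 did not pass, camera adjusted p = 0.0442, adjusted p = 0.0606 with quantile normalization, adjusted p = 0.0622 without the libraries apart), each with 0.426 or above estimated.

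**Figure D2:**
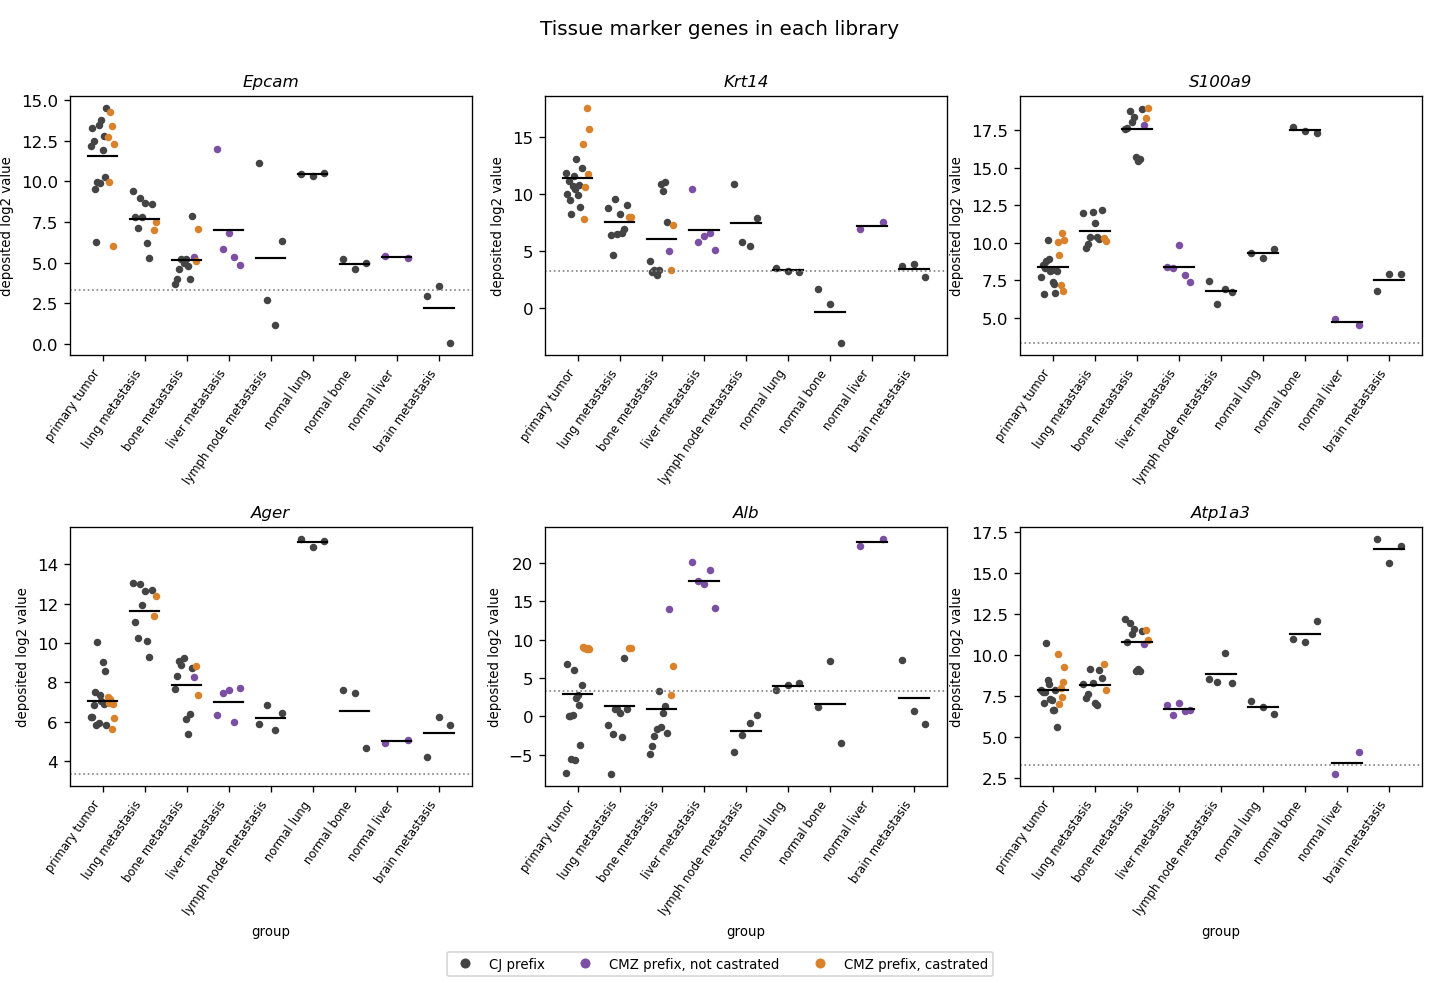
Deposited log2 value of Epcam, Krt14, S100a9, Ager, Alb and Atp1a3 in each library (points) by group, with a line at the group mean, the dotted line at the floor of 3.32 and colours for the CJ prefix and for CMZ libraries of intact and castrated mice. S100a9 averages 17.59 in bone metastases and 8.36 in primary tumors, and Atp1a3 averages 16.48 in brain metastases.

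Bone metastases were compared with normal bone (n = 3, CJ) to ask what tumor adds to the tissue around it. Krt8 and Krt18, keratins of simple epithelia, rose by 6.66 ± 0.95, adjusted p = 0.000399, 6.72 within CJ and 6.36 ± 1.01, 6.63 within CJ, and Foxa1 and Hoxb13, transcription factors of prostate epithelium, by 6.51 ± 1.18, adjusted p = 0.00179, 6.54 within CJ and at least 27.8-fold higher. Muscle and fat transcripts fell, among them Mylpf, a fast muscle light chain (-6.13 ± 1.09, -6.17 within CJ), and the lipid droplet protein Plin1 (at least 33.5-fold lower, adjusted p = 0.000679). Of 15247 genes 3061 passed, 928 higher and 2133 lower, and 3147 within CJ; 1420 passed without normal bone 2 and 1287 without normal bone 3. Strata of age and castration, with an estimated correlation of 0.52 within strata, gave 1100, 230 of them higher. A split that parted bone metastases 6, 7 and 8 from the other samples called 5146 genes. Only these bone metastases are of 8 months. If from 1 mouse, they would make p-values too small. Quantile normalization moved the median of all genes by 0.22 and the share higher from 30.3% to 54.6%.

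Among prostate identity genes of 11 members 3 rose, 0 fell and 8 did not pass (median 1.14, 0.42 floored, 4 and 0 adjusted over the list alone, camera adjusted p = 0.0086, 0.284 estimated). Steap2 rose (3.15 ± 0.88). Epithelial markers gave a larger shift, of 12 members 6 rose, 0 fell and 6 did not pass (median 3.99, 3.20 floored, 9 and 0 adjusted over the list alone, camera adjusted p = 6.29e-06, 0.284 estimated). Krt19 was among those that rose (6.02 ± 1.17). RAS-ERK output was higher, of 23 members 14 rose, 1 fell and 8 did not pass (median 1.64, 18 and 2 adjusted over the list alone, camera adjusted p = 4.36e-09, 0.292 estimated). The growth factor Lif rose by 3.64 ± 0.53, and Areg was at least 27.8-fold higher. MYC targets were higher, of 50 members 15 rose, 1 fell and 34 did not pass (median 0.60, 19 and 2 adjusted over the list alone, camera adjusted p = 4.52e-08, 0.216 estimated). Myc (1.28 ± 0.16) and Nop56 (0.64 ± 0.17) rose. TGF-beta and bone-tropism factors gave of 15 members 1 rose, 0 fell and 14 did not pass (median 0.96, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0328, 0.216 estimated, adjusted p = 0.068 within CJ, adjusted p = 0.0857 with quantile normalization). The osteoclast factor Tnfsf11 rose by 2.49 ± 0.74. Higher too were basal epithelial (2 rose, 0 fell, 3 did not pass, camera adjusted p = 0.0333, adjusted p = 0.0857 with quantile normalization, adjusted p = 0.104 without the libraries apart), cell cycle (2 rose, 0 fell, 23 did not pass, camera adjusted p = 0.0437, adjusted p = 0.119 within CJ, adjusted p = 0.466 with quantile normalization, adjusted p = 0.0547 without the libraries apart, adjusted p = 0.0661 with the length trend removed) and hypoxia and glycolysis (5 rose, 1 fell, 8 did not pass, camera adjusted p = 0.0328, adjusted p = 0.0888 with quantile normalization, adjusted p = 0.0547 without the libraries apart), each with 0.396 or above estimated. Skeletal muscle markers fell, 9 of 9 (median -6.16, camera adjusted p = 1.87e-05, 0.36 estimated). Tnni2 (-5.29 ± 1.09) fell too. Fat cell markers were lower, of 6 members 0 rose, 5 fell and 1 did not pass (median -5.59, -3.26 floored, camera adjusted p = 0.000391, 0.216 estimated). B cell markers fell, 10 of 10 (median -2.62, camera adjusted p = 0.000333, 0.396 estimated). Adipoq was -2.99 ± 0.71 and Cd22 -2.57 ± 0.62. Oxidative phosphorylation genes were lower, of 26 members 0 rose, 16 fell and 10 did not pass (median -0.93, 0 and 20 adjusted over the list alone, camera adjusted p = 4.82e-08, 0.36 estimated). Ndufs1 (-1.32 ± 0.20) fell too. Among osteoblast and osteocyte markers of 11 members 0 rose, 3 fell and 8 did not pass (median -1.98, 0 and 4 adjusted over the list alone, camera adjusted p = 0.0328, 0.553 estimated, adjusted p = 0.0547 without the libraries apart). Col1a1 fell by -2.67 ± 0.69, and Bglap and Bglap2, which share reads, were uncertain. Of the 20 lists called, lower ones also included neuroendocrine (0 rose, 6 fell, 2 did not pass, camera adjusted p = 0.000431), brain neuron and glia (0 rose, 7 fell, 3 did not pass, camera adjusted p = 1.99e-05), erythroid (0 rose, 2 fell, 8 did not pass, camera adjusted p = 0.0167) and T cell (0 rose, 4 fell, 6 did not pass, camera adjusted p = 0.00321), each with 0.216 or above estimated. Interferon and stromal lists were lower as well: interferon response (0 rose, 5 fell, 10 did not pass, camera adjusted p = 0.0144), fibroblast (0 rose, 4 fell, 4 did not pass, camera adjusted p = 0.0145) and smooth muscle (0 rose, 4 fell, 3 did not pass, camera adjusted p = 0.0145), each with 0.396 or above estimated. Marrow granulocyte markers were not called, with Prtn3 at 0.85 ± 0.79 and Ctsg at 1.14 ± 0.87, neither passing.

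Lung metastases had more dividing-cell transcripts than normal lung (n = 3, CJ). Top2a, the topoisomerase of dividing cells, rose by 5.08 ± 0.26, adjusted p = 5.01e-09, 5.11 within CJ, the mitotic kinase Cdk1 by 5.45 ± 0.30, adjusted p = 6.85e-09, 5.41 within CJ and the transcription factor Foxm1 by 4.66 ± 0.26, 4.74 within CJ. Hoxb13, a prostate transcription factor, was at least 105-fold higher, and Etv4, an ERK-induced factor, rose by 7.03 ± 0.22, adjusted p = 3.55e-11, 7.01 within CJ. Scgb1a1 (-4.47 ± 0.77, adjusted p = 0.00037, -4.29 within CJ) and Cyp2f2 (-5.54 ± 0.78, -5.27 within CJ), both of club cells, and the vessel receptor Tek (-3.93 ± 0.60, -3.72 within CJ) fell. Of 15085 genes 6496 passed, 2479 higher and 4017 lower, and 6494 within CJ. Quantile normalization moved the median of all genes by 0.24 and the share higher from 38.2% to 53.3%.

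Cell cycle genes rose: 25 of 25 (median 4.01, camera adjusted p = 1.09e-26, 0.0775 estimated). MYC targets were higher, of 50 members 40 rose, 0 fell and 10 did not pass (median 1.05, camera adjusted p = 8.95e-15, 0.388 estimated). Myc (3.39 ± 0.30) and Nop2 (1.8 ± 0.2) rose. RAS-ERK output rose, of 23 members 12 rose, 1 fell and 10 did not pass (median 1.08, 13 and 1 adjusted over the list alone, camera adjusted p = 8.61e-06, 0.388 estimated). Dusp4 (3.22 ± 0.38) rose too. Prostate identity genes gave of 9 members 5 rose, 1 fell and 3 did not pass (median 1.44, 6 and 2 adjusted over the list alone, camera adjusted p = 0.0254, 0.408 estimated, adjusted p = 0.073 with quantile normalization). The receptor Ar itself rose (2.43 ± 0.60). Among chondrocyte markers of 5 members 3 rose, 0 fell and 2 did not pass (median 2.64, 0.78 floored, camera adjusted p = 0.024, 0.388 estimated). Sox9 rose (7.21 ± 0.43). Higher as well were hypoxia and glycolysis (7 rose, 2 fell, 5 did not pass, camera adjusted p = 0.00647), TGF-beta and bone-tropism factors (6 rose, 2 fell, 6 did not pass, camera adjusted p = 0.0265, adjusted p = 0.073 with quantile normalization), osteoblast and osteocyte (4 rose, 1 fell, 1 did not pass, camera adjusted p = 0.0359, adjusted p = 0.0601 within CJ, adjusted p = 0.073 with quantile normalization), marrow granulocyte (7 rose, 0 fell, 2 did not pass, camera adjusted p = 0.0061) and oxidative phosphorylation (4 rose, 0 fell, 22 did not pass, camera adjusted p = 0.0265, adjusted p = 0.0962 within CJ, adjusted p = 0.073 with quantile normalization, adjusted p = 0.276 with the length trend removed), each with 0.408 or above estimated. Lung epithelium markers fell, 12 of 12 (median -3.80, camera adjusted p = 0.00023, 0.408 estimated). Hopx (-3.29 ± 0.59) fell too. Endothelial markers fell, 9 of 9 (median -2.33, camera adjusted p = 0.000734, 0.408 estimated). Tie1 (-2.73 ± 0.41) and Kdr (-3.21 ± 0.50) fell. Of the 16 lists called, lower ones also included T cell (0 rose, 10 fell, 0 did not pass, camera adjusted p = 0.0116), B cell (0 rose, 8 fell, 1 did not pass, camera adjusted p = 0.021), MHC class I presentation (0 rose, 7 fell, 3 did not pass, camera adjusted p = 0.00929) and smooth muscle (1 rose, 6 fell, 0 did not pass, camera adjusted p = 0.0176), each with 0.408 or above estimated. B2m was -1.58 ± 0.33. H2-K1 and H2-D1 share reads with other H2 genes and are uncertain.

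Liver metastases against normal liver (n = 2, both CMZ) gave 7603 passing genes of 14129, 3573 higher and 4030 lower. Top2a rose by 6.85 ± 0.24, adjusted p = 6.99e-06, Etv4 by 6.90 ± 0.21, adjusted p = 6.99e-06 and Krt19, a keratin of ducts and simple epithelia, by 7.25 ± 0.51, adjusted p = 5.6e-05. Cyp2e1, a hepatocyte enzyme, fell by -6.40 ± 1.22, adjusted p = 0.00382. Quantile normalization moved the median of all genes by 0.1 and the share higher from 47% to 52.3%. Of the low values in normal livers 1 and 2, 67.2% and 89.7% lay within 0.2 of whole steps of 1 read. Cell cycle genes rose, 25 of 25 (median 5.62, camera adjusted p = 3.56e-16, 0.274 estimated). Ccna2 (6.51 ± 0.22) rose too. RAS-ERK output was higher, of 23 members 20 rose, 0 fell and 3 did not pass (median 3.67, 20 and 1 adjusted over the list alone, camera adjusted p = 6.24e-09, 0.117 estimated). Dusp4 (5.13 ± 0.29) and Spry1 (3.64 ± 0.28) rose. TGF-beta and bone-tropism factors gave of 13 members 11 rose, 1 fell and 1 did not pass (median 3.86, 3.02 floored, camera adjusted p = 0.00196, 0.25 estimated). Jag1 rose (3.86 ± 0.34). Oxidative phosphorylation genes fell, 26 of 26 (median -2.34, camera adjusted p = 2.78e-11, 0.606 estimated). Sdhb (-3.12 ± 0.29) fell too. For hepatocyte markers of 12 members 0 rose, 5 fell and 7 did not pass (median -3.63, camera adjusted p = 0.0274, 0.71 estimated, adjusted p = 0.337 with quantile normalization). Apoa2 fell (-5.86 ± 1.24). For marrow granulocyte markers of 9 members 8 rose, 0 fell and 1 did not pass (median 3.65, 2.71 floored, camera adjusted p = 0.0274, 0.606 estimated, adjusted p = 0.0765 with quantile normalization). S100a9 rose (3.65 ± 0.62).

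Bone and lung metastases were compared directly (n = 12 and n = 11). Myeloperoxidase Mpo (15.16 ± 1.52 in bone) was at least 2360-fold higher, adjusted p = 2.42e-12, cathelicidin Camp rose by 10.64 ± 0.47, 10.21 within CJ, Ngp by 9.61 ± 0.54, adjusted p = 7.28e-12, 9.04 within CJ, the neutrophil protease Prtn3 by 8.43 ± 0.50, 8.01 within CJ and the red cell anion exchanger Slc4a1 by 8.98 ± 0.71, 8.73 within CJ. Eln (-5.94 ± 0.44, adjusted p = 4.24e-10, -5.85 within CJ), Sparcl1 (-4.36 ± 0.42, -4.62 within CJ), Ager, of alveolar cells (-3.77 ± 0.51, -3.81 within CJ), Ace (-3.71 ± 0.30, -3.64 within CJ) and Fmo2 (-3.57 ± 0.59, -3.61 within CJ) were lower in bone. Of 13862 genes 7012 passed, 3561 higher and 3451 lower in bone, and 5959 within CJ.

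Marrow granulocyte markers rose, 12 of 12 (median 9.02, 8.34 floored, camera adjusted p = 1.31e-15, 0.0806 estimated). Erythroid markers rose too, 10 of 10 (median 8.40, 6.65 floored, camera adjusted p = 1.24e-10, 0.112 estimated). Klf1 was at least 71.1-fold higher. Osteoclast markers were higher, 7 of 7 rose (median 3.65, 3.17 floored, camera adjusted p = 0.000107, 0.277 estimated). Acp5 (3.65 ± 0.42) rose too. Of 25 cell cycle genes 22 rose, 0 fell and 3 did not pass (median 1.20, camera adjusted p = 1.31e-09, 0.169 estimated). Bub1b (1.22 ± 0.13) and Birc5 (1.38 ± 0.18) rose. Marrow may add to this too. Of the 17 lists called, higher ones in bone also included B cell (8 rose, 0 fell, 1 did not pass, camera adjusted p = 0.000653), MYC targets (19 rose, 1 fell, 30 did not pass, camera adjusted p = 0.00292), oxidative phosphorylation (17 rose, 0 fell, 9 did not pass, camera adjusted p = 0.000107), MHC class I presentation (6 rose, 0 fell, 4 did not pass, camera adjusted p = 0.0256, adjusted p = 0.0535 with the length trend removed) and T cell (5 rose, 0 fell, 5 did not pass, camera adjusted p = 0.0364, adjusted p = 0.0599 within CJ, adjusted p = 0.0531 without the libraries apart), each with 0.378 or above estimated. Skeletal muscle and osteoblast markers were higher in bone too: skeletal muscle (9 rose, 0 fell, 0 did not pass, camera adjusted p = 1.75e-05) and osteoblast and osteocyte (5 rose, 1 fell, 3 did not pass, camera adjusted p = 0.0126, adjusted p = 0.118 within CJ), each with 0.289 or above estimated. Epithelial markers were lower in bone, of 14 members 0 rose, 11 fell and 3 did not pass (median -2.34, 0 and 13 adjusted over the list alone, camera adjusted p = 0.000107, 0.277 estimated). Epcam (-2.50 ± 0.49) and Grhl2 (at least 6.26-fold lower) fell. RAS-ERK output was lower, of 23 members 0 rose, 19 fell and 4 did not pass (median -1.35, 1 and 20 adjusted over the list alone, camera adjusted p = 1.75e-05, 0.378 estimated). Spry1 (-1.29 ± 0.16) and Dusp5 (-1.61 ± 0.26) fell. Lower in bone were also lung epithelium (0 rose, 10 fell, 2 did not pass, camera adjusted p = 4.55e-10), endothelial (0 rose, 8 fell, 1 did not pass, camera adjusted p = 0.0011), mesenchymal transition (0 rose, 8 fell, 4 did not pass, camera adjusted p = 0.00506) and smooth muscle (0 rose, 6 fell, 1 did not pass, camera adjusted p = 0.00273), each with 0.0806 or above estimated. Sftpc was at least 677-fold lower and Cdh5 -2.19 ± 0.29.

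**Figure D3:**
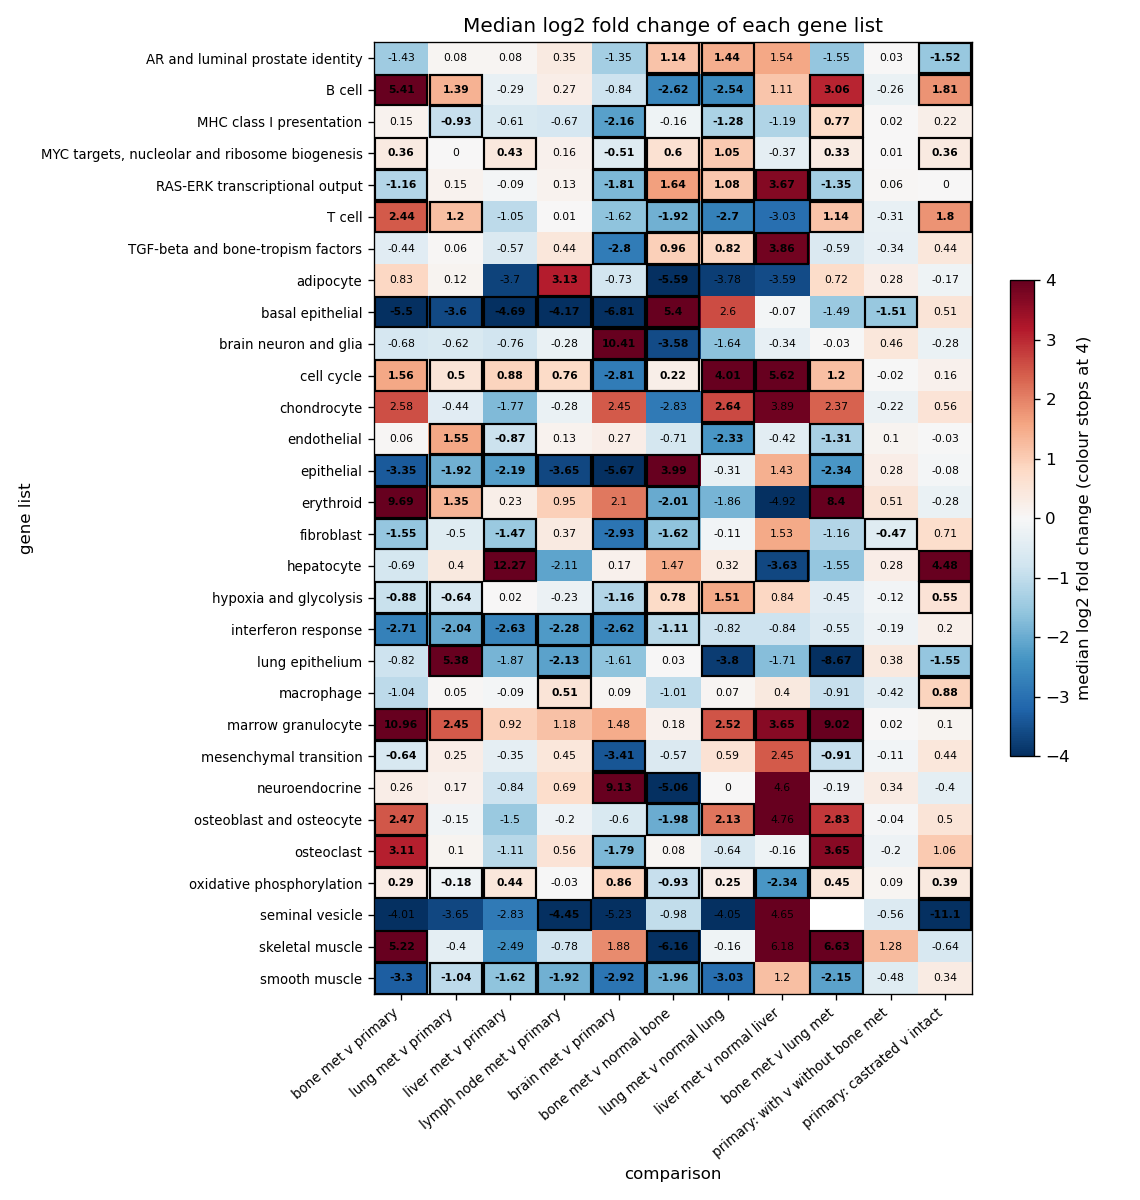
Median log2 fold change of each of 30 gene lists (vertical) in each comparison (horizontal), as colour that stops at 4 in either direction, with frames around lists called by camera. Cell cycle genes had a median of 1.56 in bone metastases and -2.81 in brain metastases against primary tumors.

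Genes outside the range of both parent tissues were asked for, since a mixture of those same tissues would lie between them. Samples that hold less muscle, fat or stroma than either parent tissue can still lie below both. Fibroblast and smooth muscle lists were lower in bone metastases than in primary tumor and in normal bone. A place below both therefore need not be a change in tumor cells. In bone metastases 213 of 13984 genes lay beyond both, 36 above and 177 below; quantile normalization gave 319, 139 above and 180 below, 168 of them shared. Lrp8, a lipoprotein receptor, rose by 1.53 ± 0.27 over primary tumor and 1.29 ± 0.31 over normal bone, the mitotic kinesin Kif20a by 1.16 ± 0.25 and 1.12 ± 0.20, and Plaur, the urokinase receptor, by 1.02 ± 0.27 and 1.17 ± 0.29. Fanca, of DNA crosslink repair (1.57 ± 0.20 and 1.12 ± 0.24), Phf19, a Polycomb cofactor (1.28 ± 0.29 and 1.44 ± 0.25), Prr7, Klhdc4 and the AMP deaminase Ampd2 rose as well. Below both were the cell adhesion protein Nfasc (at least 18.6-fold lower and at least 25.9-fold lower), the matrix protein Mfap4 (at least 22.2-fold lower and at least 16.6-fold lower), the water channel Aqp4 (at least 7.66-fold lower and at least 31.3-fold lower), Tmem45b, Lgals12, Lgi2, Htr1d and Adcy8. Within CJ 125 genes lay beyond both, 28 without normal bone 2 and 10 without normal bone 3. In limma 0 genes lay above both without normal bone 2 or 3 or with strata of age and castration (16 genes, all below). As reported, 2493 genes had an unadjusted p under 0.05, signs alike or not.

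In lung metastases 56 of 14079 genes lay beyond both, 8 above and 48 below; within CJ 20 did, and 14, 18 and 12 without normal lung 1, 2 and 3. Of these only 0, 1 and 2 lay above both. With replicate numbers as blocks 0 genes lay beyond both (limma, 1585 at an unadjusted p under 0.05 as reported, signs alike or not). Cd80, a T cell costimulator, rose by 1.82 ± 0.39 over primary tumor and 2.82 ± 0.67 over normal lung, and Trem1, of activated myeloid cells, by 1.31 ± 0.29 and 1.88 ± 0.46. Ngp (3.94 ± 0.89 and at least 12.9-fold higher), the zinc transporter Slc39a10 (1.02 ± 0.20 and 1.02 ± 0.23), Stfa2l1, Tigit, Tprkb and Paics, of purine synthesis, rose too. Below both were the hemidesmosome collagen Col17a1 (-5.84 ± 0.84 and -3.94 ± 0.88), Esrp1 (-3.16 ± 0.79 and -3.34 ± 0.70), the glutathione peroxidase Gpx2 (-3.40 ± 0.88 and -3.75 ± 0.76), Plch2, Ccdc129, Tmem30b, Cldn8 and Dpp6. Within CJ, Tigit, Tprkb, Paics, Cldn8, Gpx2 and Tmem30b did not pass against primary tumor, at adjusted p = 0.0765, 0.0862, 0.131, 0.0911, 0.0881 and 0.0973.

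In liver metastases 9 of 13823 genes lay beyond both. Above were the macrophage scavenger receptor Marco (at least 61.1-fold higher over primary tumor and 3.16 ± 0.43 over normal liver), the chromatin protein Hmgb2 (2.39 ± 0.56, 0.77 within CMZ and 4.69 ± 0.29), metallothionein Mt2 (2.29 ± 0.49, 2.23 within CMZ and 3.54 ± 0.56), Cdkn3 (1.53 ± 0.36, 1.20 within CMZ and at least 30.9-fold higher) and the helicase subunit Mcm7 (1.53 ± 0.33, 0.69 within CMZ and 2.04 ± 0.24). Below were the keratin Krt23 (-3.80 ± 0.86, -4.65 within CMZ and -3.93 ± 0.56), Lrp4 (-2.26 ± 0.52, -1.55 within CMZ and -4.20 ± 0.59), Mfhas1 (-1.02 ± 0.22, -0.89 within CMZ and -1.74 ± 0.23) and Cmtm6 (-0.67 ± 0.14, -0.55 within CMZ and -1.71 ± 0.20). No gene was called (limma) within CMZ, with quantile normalization, with the length trend removed, or without liver metastasis 2, 3 or 4. As reported, 2617 had an unadjusted p under 0.05, signs alike or not. Called were 23 without liver metastasis 5 and 102 without the libraries apart.

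**Figure D4:**
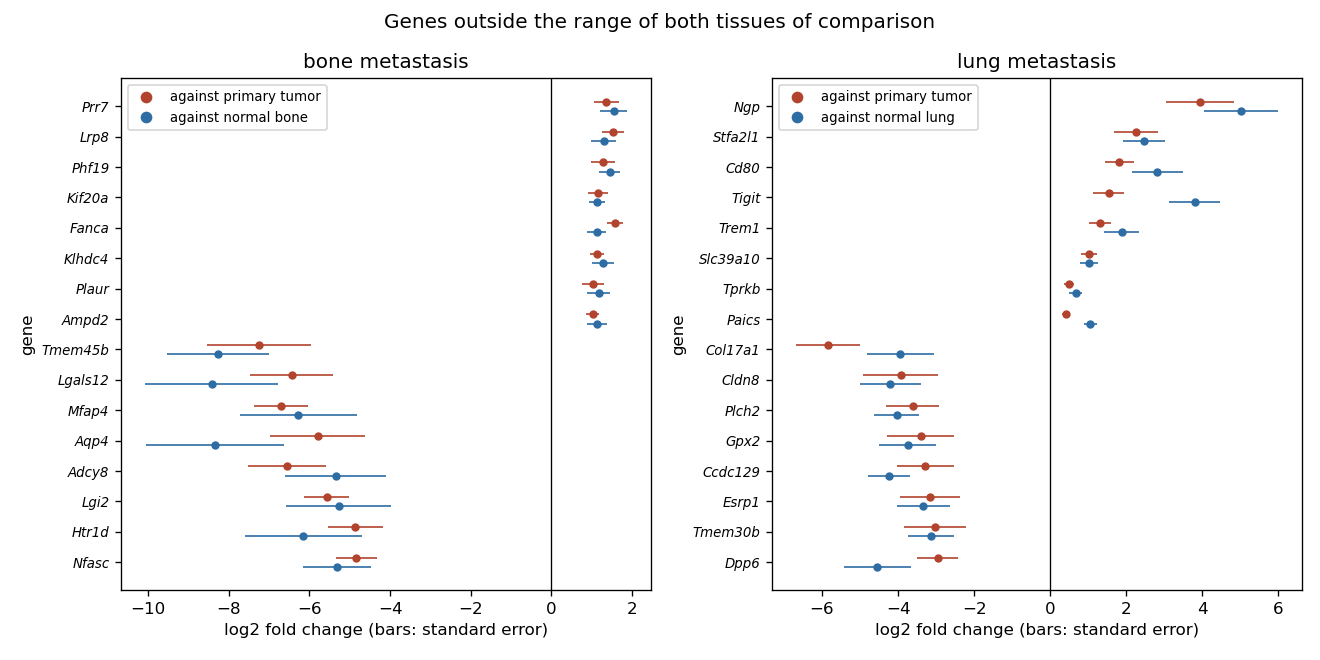
Log2 fold changes (points, with bars for the standard error) of the genes named beyond both tissues in bone and lung metastases, against primary tumor and against the normal tissue, values under the floor included as deposited. Lrp8 in bone metastases stands at 1.53 and 1.29.

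Primary tumors of mice with (n = 13) and without bone metastasis (n = 6) were compared, with castration as a covariate, for transcripts that go with spread to bone. No gene of 14395 passed in limma (0 called, 296 at an unadjusted p under 0.05). The lowest p went to Tesc (3.15 ± 0.68), Gdpd5 (1.29 ± 0.35) and Zfhx2 (0.99 ± 0.28) upward and Ifi202b (-2.67 ± 0.66), Rpl23 (-0.77 ± 0.24) and Ltbp1 (-0.67 ± 0.21) downward, none of them passing. In simulated data of this layout 34.3% of genes changed by 1 log2 unit, 77.6% changed by 2 and 81.8% changed by 3 were recovered. Basal epithelial markers were lower as a list, of 8 members 0 rose, 0 fell and 8 did not pass (median -1.51, camera adjusted p = 0.0179, 0.962 estimated, adjusted p = 0.0667 within CJ, adjusted p = 0.0507 without the libraries apart). Krt5 had -2.01 ± 1.21 and Trp63 -1.56 ± 0.97, neither passing. Fibroblast markers were lower as a list, of 8 members 0 rose, 0 fell and 8 did not pass (median -0.47, camera adjusted p = 0.0179, 0.962 estimated, adjusted p = 0.689 within CJ). Postn had -1.09 ± 0.57, not passing.

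Primary tumors of castrated (n = 6) and intact mice (n = 13) were compared, with bone metastasis status as a covariate; castration coincides with the CMZ prefix, so these differences cannot be told apart from those between the sets of libraries, unless CMZ libraries of intact mice show them too. Tgm4, a secretory transglutaminase of the prostate, was at least 28-fold lower, adjusted p = 1.56e-08, and the androgen receptor Ar fell by -2.21 ± 0.28, adjusted p = 1.14e-05. Seminal vesicle secretion genes were lower, of 5 members 0 rose, 4 fell and 1 did not pass (median -11.10, -5.34 floored, camera adjusted p = 6.06e-05, 0.268 estimated). Svs5 (at least 34-fold lower, adjusted p = 3.28e-05) and Svs2 (at least 55.7-fold lower, adjusted p = 0.00136) fell. Mesothelin Msln (-3.90 ± 0.68, adjusted p = 0.000428), Mid1 (-3.10 ± 0.20, adjusted p = 9.6e-10), Coro2a (-2.66 ± 0.31), the integrin Itga2 (-2.39 ± 0.37), Ralgps2 (-2.32 ± 0.46), Hnf1b (-2.21 ± 0.57) and Mgat3 (-2.07 ± 0.54) fell. Among well expressed genes the largest changes were those of ribosomal proteins and a few others: Rpl17 (7.30 ± 0.29), Rps12 (7.18 ± 0.31), Gapdh (6.63 ± 0.41), Rpl9 (6.56 ± 0.24), Rps6 (6.06 ± 0.29), Rpl12 (6.02 ± 0.24), Uba52 (5.37 ± 0.31) and Rpl3 (5.22 ± 0.70) rose and Ubb fell (-7.25 ± 0.25), uncertain where pseudogenes share sequence. Castration as cause of these changes is argued against by intact mice. Their median shift was 4.05 in 6 CMZ and -0.93 to 0.72 in 25 CJ metastases. Gapdh was 15 to 16.6 in normal livers (intact, CMZ) and 5.32 to 5.85 in normal lungs (CJ). Of 14395 genes 1625 passed, 777 higher and 848 lower, 4044 without the libraries apart and 1313 with the length trend removed.

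Prostate identity genes gave of 10 members 0 rose, 4 fell and 6 did not pass (median -1.52, -1.22 floored, 1 and 4 adjusted over the list alone, camera adjusted p = 0.006, 0.166 estimated, adjusted p = 0.0549 without the libraries apart). Foxa1 (-1.54 ± 0.44) and Steap2 (-1.49 ± 0.44) fell. Hepatocyte markers were higher, of 11 members 6 rose, 0 fell and 5 did not pass (median 4.48, 1.61 floored, 8 and 0 adjusted over the list alone, camera adjusted p = 2.86e-06, 0.0592 estimated). Alb was at least 32.3-fold higher, adjusted p = 0.00322, with a mean of 8.88 ± 0.08 in castrated mice. MYC targets were higher, of 50 members 12 rose, 1 fell and 37 did not pass (median 0.36, 13 and 1 adjusted over the list alone, camera adjusted p = 2.86e-06, 0.556 estimated). Oxidative phosphorylation genes were so too, of 26 members 9 rose, 0 fell and 17 did not pass (median 0.39, 12 and 0 adjusted over the list alone, camera adjusted p = 4.5e-06, 0.556 estimated, adjusted p = 0.166 with the length trend removed). Odc1 rose by 1.55 ± 0.17 and Cox5b by 4.10 ± 0.22. For hypoxia and glycolysis of 14 members 4 rose, 0 fell and 10 did not pass (median 0.55, 6 and 1 adjusted over the list alone, camera adjusted p = 0.00257, 0.556 estimated). Pgk1 rose (2.53 ± 0.24). Among lung epithelium markers of 11 members 0 rose, 4 fell and 7 did not pass (median -1.55, -0.77 floored, 0 and 5 adjusted over the list alone, camera adjusted p = 0.0115, 0.556 estimated, adjusted p = 0.0722 without the libraries apart). Lamp3 was at least 4.58-fold lower. Leukocyte lists were higher: for B cell of 4 members 2 rose, 0 fell and 2 did not pass (median 1.81, 0.96 floored, 3 and 0 adjusted over the list alone, camera adjusted p = 0.0393, 0.556 estimated, adjusted p = 0.108 without the libraries apart, adjusted p = 0.0644 with the length trend removed), and for T cell of 10 members 0 rose, 0 fell and 10 did not pass (median 1.8, 0.42 floored, camera adjusted p = 0.0447, 0.89 estimated, adjusted p = 0.176 without the libraries apart, adjusted p = 0.091 with the length trend removed). Macrophage markers were higher as a list, of 9 members 0 rose, 0 fell and 9 did not pass (median 0.88, 3 and 0 adjusted over the list alone, camera adjusted p = 0.0447, 0.845 estimated, adjusted p = 0.0631 without the libraries apart, adjusted p = 0.0985 with the length trend removed). Cd22 was 1.13 ± 0.34, and Cd68 had 0.82 ± 0.26, not passing.

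**Figure D5:**
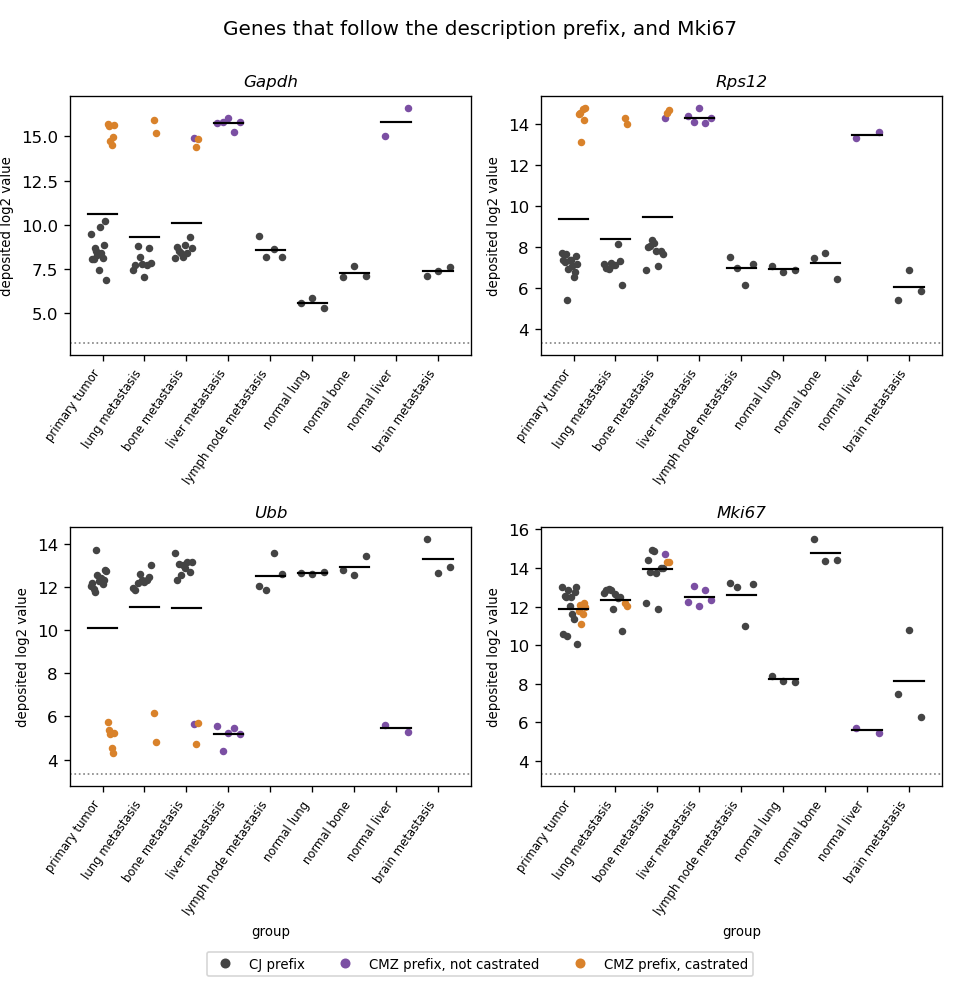
Deposited log2 value of Gapdh, Rps12, Ubb and Mki67 in each library (points) by group, with a line at the group mean, the dotted line at the floor of 3.32 and colours for the CJ prefix and for CMZ libraries of intact and castrated mice. Gapdh lies at 15 or above in CMZ liver libraries and at 9.36 or below in CJ lymph node libraries.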

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

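Tests chosen only after the results were seen were those of castration, of gene length, of liver reads and of bone tissue and library sets below, and the counts of other splits of the samples.

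Cdkn3, a phosphatase of dividing cells, was 8.65 in liver metastasis 5 and between 8.14 and 8.23 in the other liver metastases, which set that sample apart. Rps12 was 13.15 in primary tumor 16, below the other castrated primary tumors at 14.23 to 14.81. These were 2 of 53 gene-by-group tests, and chance picks out about 1 in 20 groups.

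The change from normal tissue to metastasis differed between bone and lung in 1830 of 16129 genes (interaction term, limma; 758 higher and 1072 lower in bone, 4055 at an unadjusted p under 0.05). Cell cycle genes differed most (median -3.79, camera adjusted p = 1.48e-44, 0.000685 estimated). Mki67 was at least 14.38 in normal bone and at most 8.42 in normal lung, so weaker division in bone metastases is not shown. No other list called with the preset correlation held (0.128 to 0.552 estimated). In camera with its preset correlation, medians were below 0 for oxidative phosphorylation (-1.24, adjusted p = 2.25e-12), skeletal muscle (-6.42, adjusted p = 2.89e-05), MYC targets (-0.5, adjusted p = 4.58e-05) and neuroendocrine genes (-3.82, adjusted p = 0.000374). The same held for osteoblast and osteocyte (-4.05, adjusted p = 0.00198), chondrocyte (-4.89, adjusted p = 0.00238), marrow granulocyte (-1.91, adjusted p = 0.0153), macrophage (-0.79, adjusted p = 0.0278), brain (-1.34, adjusted p = 0.0438) and mesenchymal genes (-0.82, adjusted p = 0.048). Medians were above 0 for epithelial (3.69, adjusted p = 1.74e-05), lung epithelium (3.13, adjusted p = 0.000208), endothelial (1.97, adjusted p = 0.000293) and MHC class I genes (1, adjusted p = 0.0036). The effect of bone metastasis status did not differ by castration in any of 14395 genes (limma, 0 called, 301 at an unadjusted p under 0.05).

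Ribosomal protein genes were higher in castrated primary tumors (71 of 79 tested passed upward and 0 downward, median 3.34), with Gapdh and Uba52, while Ubb was lower. Castration of the mouse as the cause is argued against by intact mice. Their median shift was 4.05 (3.79 to 4.51) in 6 CMZ and -0.93 to 0.72 in 25 CJ metastases. Gene length as the whole cause is argued against by a median of 3.06 with the length trend removed (lower quartile 1.41, 3.37 as reported). It covers all 82 genes of these families, passing or not. A candidate explanation is reads shared with pseudogenes and counted differently in the CJ and CMZ libraries, since medians of genes with at least 5 pseudogenes (149 genes, 1.52) and with none (11479 genes, -0.04) differed by 1.56. Without ribosomal protein genes the first median was 0.88 over 99 genes, and ribosomal protein genes with at least 5 copies had 4.64 against 1.85 for the 28 others. Gapdh shares sequence with 179 pseudogenes, Uba52 with 5 and Ubb with 1, so the fall of Ubb stays open.

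Hepatocyte transcripts lay at a nearly constant level in castrated primary tumors: Alb was 8.76 to 9.00 there, 8.94 and 8.96 in lung metastases 10 and 11, and at most 6.82 in intact primary tumors. Reads carried over from liver libraries may be the source: over 30 liver transcripts the gap to normal liver had an SD of 0.36 around 13.82, with a rank correlation across genes of 0.89, genes being no independent replicates. Only 13 of the 30 transcripts reached the floor in all castrated primary tumors, and a fixed share of liver RNA from any source gives the same values. Against a share common to all CMZ libraries stand bone metastases 10, 11 and 12, with Alb at 14.02, 2.73 and 6.57. Castration and the CMZ set cannot be told apart here, as 0 primary tumors or lung metastases of intact mice carry that prefix.

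Epithelial and basal epithelial transcripts were lower in bone metastases than in primary tumors (median -4.69 over both lists). Bone tissue mixed in as the whole cause lowers all tumor transcripts alike. In 59 transcripts under the floor in normal bone, floored changes ran from -5.77 to -1.65 (10th to 90th percentile). That width was 4.12 (7.75 unfloored), where fitted error gives 1.66. The floor caps falls (Krt5) and floored libraries do not vary, so 1.66 may be too small. The CJ and CMZ sets are argued against by a median of -4.15 within CJ (22 members, upper quartile -2.3). Mixing stays open. Nontumor epithelium in primary samples and a change in tumor cells were not tested.

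Other splits of the samples excluded chance for bone metastasis against primary tumor (7163 genes, highest other 0), with 1 of 100 splits as large, the real one included. The same count of 1 excluded it for liver (2890, highest other 846) and brain metastasis (8427, highest other 3306) against primary tumor, lung metastasis against normal lung (6496, highest other 221), bone against lung metastasis (7012, highest other 2501) and castration (1625, highest other 197), whose split follows the library prefix. Chance was also excluded, with 2 of 100 splits as large, for lung metastasis against primary tumor (918, highest other 2538) and bone metastasis against normal bone (3061, highest other 5146, which parted bone metastases 6, 7 and 8 from the rest). Chance was not excluded for lymph node metastasis (6 of 100, with 95 genes and highest other 5664). For bone metastasis status 100 of 100 tests nothing, as every split calls at least as many as 0 genes (limma, 296 at an unadjusted p under 0.05, highest other 66). Splits that called several times the real count point to a structure of the samples: in the lymph node comparison all 5 put primary tumor 5 and lymph node metastasis 3 together. For genes beyond both tissues in bone (213, highest other 0) and lung (56, highest other 0) 1 of 100 splits was as large too. Such splits mix tumor and normal tissue in every group and cannot test a place beyond both, so chance stays open there as well. Liver metastasis against normal liver and beyond both tissues was not split, since groups of fewer than 3 samples were left out.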

How the results depend on the processing

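Chosen after the data were seen were the alternatives added later and, for lists, 1 prefix only. Of the counts under alternatives 139 stayed within 1.5 times the reported count and 62 did not; of list results 2530 kept direction and side of the threshold, 91 gained a call, 247 lost one and 1 reversed; of named genes these were 12662, 235, 1097 and 2. No gene was called for bone metastasis status under any alternative run (limma, 0; 296 at an unadjusted p under 0.05 as reported). Bone metastasis against primary tumor and bone against lung stayed within 1.5 times under all alternatives run.

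Array weights gave 1677 genes for lung, 7071 for liver and 216 for lymph node metastasis against primary tumor, 8622 and 10135 for bone and lung metastasis against normal tissue, 4741 for castration, and 2749, 362 and 239 beyond both tissues in bone, lung and liver. One fit over all groups gave 345 for lymph node and 416, 19 and 87 beyond both tissues in bone, lung and liver. Strata of age and castration gave 149 for lymph node, 1100 for bone against normal bone, and 16, 30 and 131 beyond both. Replicate numbers as blocks gave 487 for lung, 1125 for liver, 0 for lymph node (95 and 1339 at an unadjusted p under 0.05 as reported), 5304 for brain, 1459 for bone against normal bone, 4456 for liver against normal liver, and 20, 0 (56 and 1585 at an unadjusted p under 0.05 as reported) and 4 beyond both in bone, lung and liver. CJ libraries only gave 125 and 20 beyond both in bone and lung, and the prefix as a covariate 1760 for liver and 358 beyond both in bone. CMZ libraries only gave 3 for lung, 1614 for liver and 0 beyond both in liver, where quantile normalization and removal of the length trend also gave 0 (limma, 2617 at an unadjusted p under 0.05 as reported). Flooring gave 2 for lymph node and 358 and 96 beyond both in bone and lung. Without the libraries apart there were 4613 for liver, 38 for lymph node, 4044 for castration and 102 beyond both in liver. Fewer samples remain in the 1-prefix, block and leave-out settings; otherwise the cause was not tested.

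Leaving out 1 replicate at a time gave 1828 to 2418 genes for liver and 1 to 113 for lymph node against primary tumor, 1287 to 2133 for bone against normal bone, and 10 to 144, 12 to 18 and 0 to 23 beyond both in bone, lung and liver. The extremes were without liver metastases 4 and 5, lymph node metastases 3 and 1, normal bones 3 and 1 (both for bone), normal lungs 3 and 2, and liver metastases 2 and 5. Leaving out 1 normal liver leaves 1, assumed to vary like the metastases.

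Of 138 list calls, an estimated correlation left 5, fry gave 143 (113 shared), no filter 147 (136 shared), quantile normalization 134 (126), array weights 127 (114), 1 prefix 145 (128), without the libraries apart 124 (119) flooring 130 (125) and removal of the length trend 132 (129). The cell cycle list turned upward for bone metastasis status under array weights (adjusted p = 0.000972, 0.702 as reported, 0.000972 to 0.97 over the alternatives). Ubb in liver metastasis against primary tumor turned from -4.91 to 0.12 with the prefix as a covariate and to 0.12 in CMZ only.

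Between bone and lung metastases the mean correlation was 0.12 for samples with the same number and -0.01 for others (11 pairs, permutation p = 0.052). By their labels several of these pairs differ in age or castration, or hold a lung metastasis of a mouse without bone metastasis. Those pairs cannot come from 1 mouse, so the numbers do not stand for mice there. With blocks 6590 genes passed. In the other comparisons the mean correlation was -0.14 to 0.05 for the same number (permutation p = 0.13 to 1). A pseudocount was not applied, the values being logarithms. The prefix could not be a covariate for castration or liver against normal liver, where it is fixed by the groups, nor for bone metastasis status, where castration already carries it. Groups with fewer than 2 samples of a prefix gave no value. Depth per library is unknown, so changes near the floor are limited to an unknown degree.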

Other observations

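Genes in this part were chosen after their values were seen. Of 59 transcripts above 8 in primary tumors and under the floor in normal bone, the keratin Krt5 (-7.72), the immunoglobulin receptor Pigr (-7.68) and Esrp1 (-6.24) had the lowest floored log2 changes in bone metastases. The water channel Aqp5 (-0.35), the growth factors Areg (-0.98) and Ereg (-1.46), the gap junction protein Gjb4 (-1.39), the phospholipase Plch1 (-1.42) and the transcription factors Sall3 (-1.5) and Hoxa13 (-1.69) had those smallest in size, and no test of single genes is given here. Keratins spread over the range, with Krt14 at -5.32, Krt17 at -5.31, Krt6a at -3.23, Krt4 at -2.64, Krt13 at -2.34 and Krt15 at -2.32.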
